A study of Bos taurus with 12 samples.

How the data were processed

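Gene expression was measured by RNA-seq in peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes that a Ficoll density gradient separates from blood. The animals were 6 dairy cows, and each gave a sample 21 days before calving and another 7 days after it, so there were 12 libraries. Per the labels, cows 1 to 3 formed group L and cows 4 to 6 formed group H, which had shown more signs of metabolic stress in other assays. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was selected, and strand-specific libraries were prepared.

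Per the submitters' processing notes, cutadapt 1.8, TopHat2 2.1.1, Cuffdiff 2.2.1 and the cattle genome build UMD3.1 were used. The annotation release, the read filters and the strand setting of the counting are not given in the sources used here, so fragments of overlapping genes or of near-identical gene copies may have been divided between them. The table used here held 24616 genes in each of the 12 libraries. The authors deposited an estimated count of fragments per gene and library, without normalization. Of the 295392 values, 369 in 45 genes were not whole numbers at a tolerance of 1e-06, and 6922 genes were at 0 in every library after rounding. A status of failed estimation stood beside 8 values in 2 genes. Per the file headers, the deposited internally scaled fragments are a normalized signal, and they equalled the raw fragments multiplied by a constant for each library. The authors also deposited FPKM values, in which fragments are scaled by transcript length and by the library's mapped fragments.

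The estimated counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filterByExpr filter and Benjamini-Hochberg adjustment. Genes with an adjusted p below 0.05 were called. The postpartum and prepartum libraries were compared in a fit of 2 groups of 6. The change within L, the change within H, the difference between these changes (the interaction), and H against L at each time came from a fit of 4 groups of 3, which share an estimate of the spread. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels in CPM, counts scaled to a common library total, used TMM-scaled library sizes, and changes within a cow were differences of log2 CPM with a prior count of 1. Values of libraries or of cows were compared with two-sided exact permutation tests of the difference of means, which took the libraries as unpaired. A sign-flip test of the differences within cows was added after the data had been seen. The length of a gene was taken from the ratio of its scaled fragments to its FPKM. The comparisons, tests, gene rule and most alternatives were fixed before the data were examined.

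The main fits had no term for the cow, because Cuffdiff takes none. The same animals were sampled at both times per the labels, so the cow numbers pair the libraries. The correlation across genes of a cow's paired deviations from the group means was 0.611, 0.554, 0.416, 0.57, 0.559 and 0.438 for cows 1 to 6, and each was above the cow's highest correlation with another cow of its group at the later time. Fits with the cow as a block were made beside the main ones. Other settings were DESeq2 1.42.0, median-of-ratios size factors, no filter on low counts, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), a fit of only the 2 groups compared, limma-voom with the cow as a random effect, and leaving out each library in turn. Scaling by library totals alone, leaving out cow 5, a blocked fit of each group's own 6 libraries, removing a trend on gene length, and thinning all libraries to 11687673 fragments were added after the data had been seen. No pair of libraries of the same group agreed within sampling noise (chi-square per degree of freedom from 10.09 to 157.3 over genes), so all 12 were kept as separate samples.

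The files used here pair no gene identifier with a gene name. The reference table used for names, of assembly ARS-UCD2.0, matched 0 of the 24616 identifiers. None of the 30 gene lists fixed beforehand could therefore be tested, and cell types and pathways were not analysed here. The rule for named genes took those with a symbol, a mean of at least 1 CPM, an adjusted p below 0.05 and the same direction in every cow of the comparison, in order of size. Its symbol condition could not be met. In its place 2 identifiers that rose and 2 that fell are printed, and this departure was made after the data had been seen. They are the gene called over all 6 cows and, by the rest of the rule, the largest rise and the 2 largest falls in H.

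The edgeR fits were tested on simulated counts for the real genes, with 200 genes changed by known folds. For the change within L, with 12589 genes tested, 38.8% of the 2-fold and 80.3% of the 4-fold changes were recovered. For the change within H, with 12603 genes, the shares were 41.8% and 83.3%. For the 6 against 6 comparison, with 12339 genes, they were 68.7% and 92.4%. For the interaction, with 12597 genes, they were 8.96% and 56.1%. They were 38.8% and 81.8% for H against L before calving, with 12592 genes, and 35.8% and 84.8% after calving, with 12615 genes. Between 1 and 5 unchanged genes were called in each. The simulation gave all groups the same spread between cows, which the real groups did not have. It also drew the libraries of a cow independently, while the real ones were correlated within cows.

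Library totals ranged from 11.69 to 19.72 M (mega) fragments. Counting intervals cover counting error only. The cows were separate animals, so p-values rest on the spread between these cows. In the fit of 4 groups this spread was pooled over all groups, so p-values in H rest in part on the L cows. Fits without a block took the libraries of a cow as independent, so their p-values do not measure the spread of changes within cows.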

Results

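PBMC from 6 dairy cows were profiled 21 days before and 7 days after calving, a period in which energy demand rises with the onset of lactation. Group H (3 cows) had shown more metabolic stress in other assays than group L (3 cows). The 12 libraries fell into 4 groups of 3, formed by group and time. Before calving, the totals were 19.72, 17.31 and 11.69 M (mega) fragments in L cows 1 to 3 and 16.39, 15.14 and 13.93 M in H cows 4 to 6. After calving, they were 17.54, 16.72 and 15.97 M in L and 18.69, 18.64 and 15.79 M in H. The mean totals were 16.24 ± 4.12 M in L before calving, 15.15 ± 1.23 M in H before calving, 16.74 ± 0.785 M in L after calving and 17.71 ± 1.66 M in H after calving (SD, n = 3 each). The totals after and before calving differed by 1.53 M fragments, less than the spread between libraries (exact permutation p = 0.255, adjusted 0.395 over the family of 25 library tests). H and L differed by -1.09 M before calving (exact permutation p = 0.8, adjusted 0.87) and by 0.963 M after it (exact permutation p = 0.4, adjusted 0.476). With 3 libraries against 3 the smallest p that this test can give is 0.1.

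The first principal component of log2 CPM held 31.4% of the variance and the second 20.9%. The postpartum libraries of H scored 6.321, 83.63 and 28.09 on the first component for cows 4, 5 and 6, and those of L scored between -5.906 and 2.59. Over the 6 cows its mean score was 18.8 after calving and -18.8 before it, a difference that did not pass after adjustment (exact permutation p = 0.00649, adjusted 0.0541 over the 25 tests). Within cows the score was higher after calving in 6 of 6, and the TMM factor was lower in 6 of 6. For each, an exact sign-flip permutation test of the 6 differences gave p = 0.0312, the smallest it can give, and 0.052 after adjustment over 5 measures. The 20 most abundant genes held 9.92% of the fragments after calving and 9.04% before it, which did not pass after adjustment either (exact permutation p = 0.0238, adjusted 0.149). By group, the share was 8.91 ± 0.203% in L and 9.17 ± 0.45% in H before calving, and 9.5 ± 0.563% in L and 10.3 ± 0.732% in H after calving (SD, n = 3 each). The biological coefficient of variation between cows was 17.1% in L and 22.3% in H before calving, and 25.1% in L and 31.8% in H after calving. In H after calving, cows 4 and 6 were closer to each other than to cow 5 (chi-square per degree of freedom 31.23 against 157.3 and 112).

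**Figure D1:**
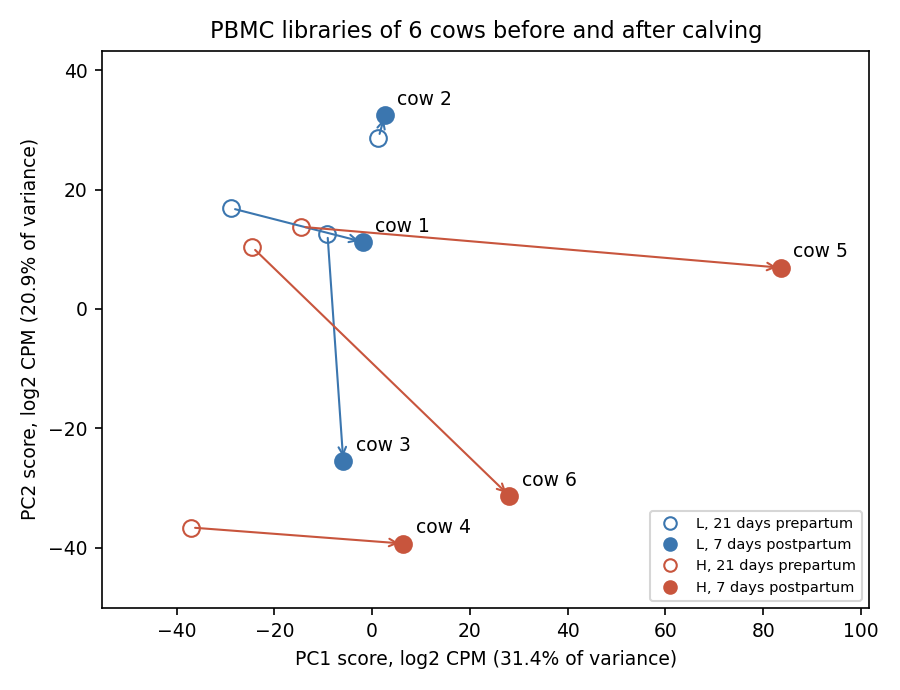
Principal component scores of log2 CPM for the 12 libraries, with the first component (31.4% of the variance) on the horizontal axis and the second (20.9%) on the vertical axis. Open circles are libraries from 21 days prepartum, filled circles those from 7 days postpartum, blue is group L, red is group H, and each arrow joins the libraries of a cow; the postpartum library of cow 5 lies at 83.63 on the first component.

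The comparison of all 6 postpartum with all 6 prepartum libraries asked which transcripts changed around calving whatever the group. ENSBTAG00000046218 rose, with a log2 fold change of 1.65 ± 0.213 (SE, n = 6 against 6, adjusted p = 0.0336 in edgeR's quasi-likelihood test), and it was higher after calving in 6 of 6 cows. Its level was 13.1 ± 2.71 CPM in L and 14.4 ± 6.94 CPM in H before calving, and 36.3 ± 5.02 CPM in L and 50.3 ± 7.2 CPM in H after calving (SD, n = 3 each). It was the only gene called by edgeR among 12314 tested. DESeq2 called 644 genes, 543 higher and 101 lower, and edgeR gave 2582 genes an unadjusted p under 0.05, where 616 would be expected with no change. With the cow as a block no gene was called: ENSBTAG00000046218 had a log2 fold change of 1.68 and an adjusted p of 0.0553 in edgeR, within a range of 0.0553 to 0.147 over the 10 alternatives in which its call was lost. Leaving out the postpartum library of L cow 2 raised the count to 1035 genes, and leaving out any other library gave between 0 and 7.

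In the 3 cows of group H, 1516 of 12696 genes changed after calving, 1219 of them higher and 297 lower. The risen genes had a median log2 fold change of 1.02 (quartiles 0.662 and 1.61), and 621 of them rose more than 2-fold. The fallen genes had a median of -0.807 (quartiles -1.09 and -0.603), and 91 fell more than 2-fold. These are calls of edgeR's quasi-likelihood test, in which 3687 genes had an unadjusted p under 0.05 against 635 expected. The split between rises and falls depended on the scaling. Median-of-ratios factors gave 1070 higher and 365 lower genes, 74.6% higher against 80.4% with TMM. With library totals as the only scaling, 1721 genes were called, 778 higher and 943 lower (45.2% higher), and the median log2 fold change of all genes was -0.193, against -0.00233 with TMM. TMM factors after calving in H were 0.9426, 0.8575 and 0.936 for cows 4, 5 and 6, against 1.011 to 1.063 in the 6 prepartum libraries. With the cow as a block 2460 genes were called, 1658 higher and 802 lower, and these included 1485 of the 1516. A fit of the 6 H libraries alone called 287 genes without a block, 285 higher and 2 lower, and 1654 with it, 1253 higher and 401 lower, and DESeq2 on all libraries called 2314. The count was 997, 454 and 543 without the prepartum library of cow 4, 5 or 6. It was 2056, 706 and 766 without the postpartum library of cow 4, 5 or 6. The number of falls changed most: it was 389, 16 and 15 without the prepartum library of cow 4, 5 or 6, 699, 138 and 75 without the postpartum library of cow 4, 5 or 6, and 696 without that of L cow 3. It was 173 and 132 without the prepartum library of L cow 2 or 3.

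The 4 printed identifiers gave the following values. Their rule required the same direction in every cow of the comparison, so that direction is no separate support. ENSBTAG00000017866 rose by a log2 fold change of 7.28 ± 1.25 (SE, n = 3 against 3, adjusted p = 0.00593 in edgeR) and was higher after calving in 3 of 3 H cows. It had 5 fragments in the 3 prepartum H libraries, 1 to 3 in each, and 855 in the 3 postpartum libraries, a ratio of 167 after scaling for library size, with a 95% counting interval from 71.4 to 517. Without the postpartum library of cow 5 its log2 fold change was 6.45. Its level after calving was 17.6 ± 13 CPM in H and 1.54 ± 1.73 CPM in L (SD, n = 3 each), a difference that was not called (adjusted p = 0.0879 in edgeR), and its interaction was not called either (adjusted p = 0.529 in edgeR). ENSBTAG00000046218 rose 3.48-fold in H, with an SE of 0.289 on the log2 scale (adjusted p = 0.00488 in edgeR), and was higher in 3 of 3 H cows. ENSBTAG00000030814 fell, with a log2 fold change of -2.40 ± 0.583 (adjusted p = 0.0245 in edgeR), from 2.46 ± 2.08 to 0.463 ± 0.155 CPM, and was lower in 3 of 3 H cows. ENSBTAG00000021807 fell, with a log2 fold change of -2.33 ± 0.546 (adjusted p = 0.0214 in edgeR), from 32.6 ± 23.2 to 6.47 ± 4.29 CPM, and was lower in 3 of 3 H cows. Both falls lost their call in 5 alternatives, among them leaving out the prepartum library of cow 6. Without it the log2 fold change of ENSBTAG00000030814 was -1.44 (adjusted p = 0.0927 in edgeR, range 0.0511 to 0.0927 over the alternatives that lost the call). That of ENSBTAG00000021807 was -1.59 (adjusted p = 0.0872 in edgeR, range 0.0656 to 0.0872).

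**Figure D2:**
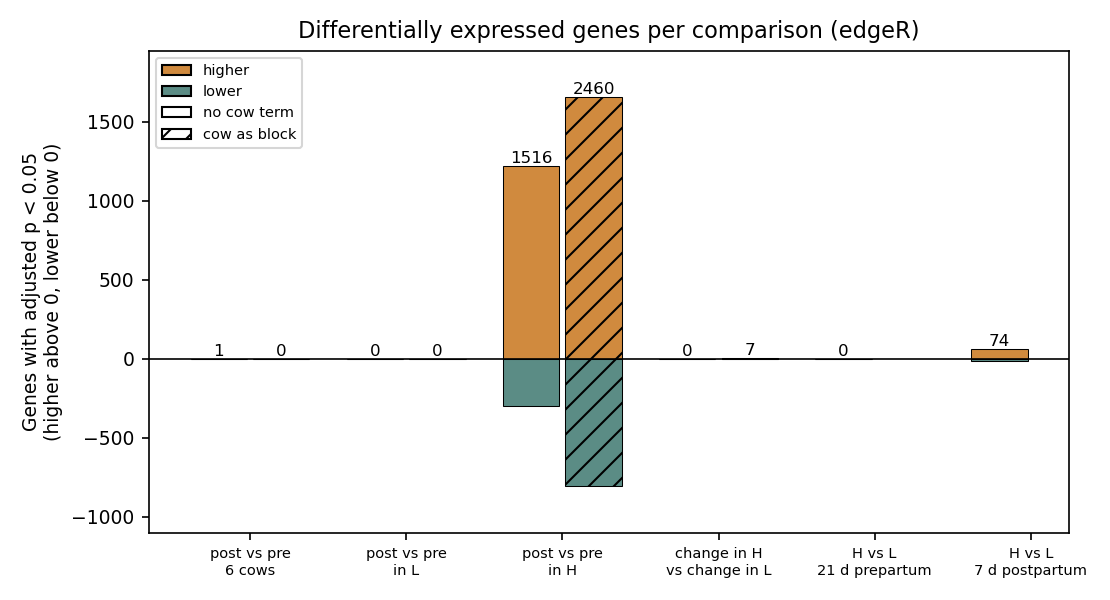
Number of genes with an adjusted p below 0.05 in edgeR's test for each comparison, with genes higher in the group or time named first above 0 and lower genes below 0. Plain bars are fits without a term for the cow and hatched bars are fits with the cow as a block, which cannot be made for H against L; the change after calving in H gave 1516 and 2460 genes, and the number above each pair of bars is their total.

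In the 3 cows of group L no gene passed the threshold among 12696 tested with edgeR, and the smallest adjusted p was 0.323. In edgeR 93 genes had an unadjusted p under 0.05, fewer than the 635 expected with no change. This number was 197 with the cow as a block and 572 without the postpartum library of L cow 2, where 644 would be expected. In the 6 L libraries alone with the block it was 287, where 622 would be expected. Such a shortfall can mean that the test was cautious in L, so 0 calls do not show that nothing changed. DESeq2 called 5 genes, 3 higher and 2 lower, limma on log2 FPKM called 0, and edgeR with the cow as a block called 0 in the fit of 12 libraries and 1 in a fit of the 6 L libraries alone. In L the log2 fold changes, none of them called, were 1.47 ± 0.287 for ENSBTAG00000046218, 3.13 ± 1.21 for ENSBTAG00000017866, -0.63 ± 0.54 for ENSBTAG00000030814 and 0.03 ± 0.513 for ENSBTAG00000021807 (SE, n = 3 against 3). ENSBTAG00000017866 was at 0 CPM before calving in L cows 1 and 2 and at 3.53 and 0.633 CPM after it, and in cow 3 it was at 0.653 CPM before and 0.45 CPM after.

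The genes called in H were then followed in L, which shares no library with H. Of the 1219 risen genes, 1109 (91.0%) were also higher after calving in L, with a median log2 fold change of 0.168 there. Of the 297 fallen genes, 278 (93.6%) were also lower, with a median of -0.171. These shares are across genes, which are not independent replicates. Among the risen genes, 93.5%, 50.5% and 71.3% were higher after calving in L cows 1, 2 and 3. Among the fallen genes, 91.2%, 41.8% and 88.6% were lower. Unadjusted p was under 0.05 in L for 47 of the 1516 genes, against 93 of all 12696 tested (0.733%).

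The difference between the change in H and the change in L was tested as an interaction. No gene passed with edgeR among 12696 tested, where the smallest adjusted p was 0.229 and 1290 genes had an unadjusted p under 0.05 against 635 expected. With the cow as a block 7 genes passed, all with a more positive change in H, and DESeq2 without a block called 133, of which 130 were more positive in H. Limma on log2 FPKM called 0.

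The size of change was also measured per cow. Among 11871 genes with a mean of at least 1 CPM, 2.38%, 0.809% and 4.44% differed more than 2-fold between the times in L cows 1, 2 and 3, and 6.39%, 19.8% and 12.7% in H cows 4, 5 and 6. The means were 2.54 ± 1.82% in L and 13 ± 6.71% in H (SD, n = 3 each). All 3 H cows lay above all 3 L cows (exact permutation p = 0.1, the smallest that 3 against 3 can give). The median absolute log2 change was 0.172, 0.111 and 0.274 in L and 0.192, 0.435 and 0.392 in H (exact permutation p = 0.2, n = 3 each).

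**Figure D3:**
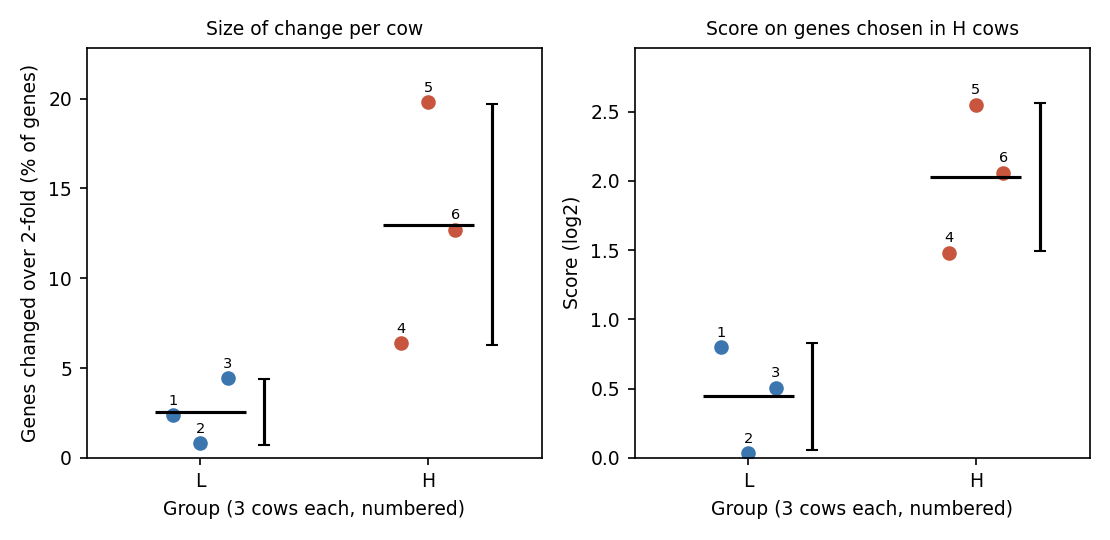
Left, percent of 11871 genes that differed more than 2-fold between the times in each cow; right, a score per cow, the median log2 change of 200 genes risen minus that of 200 genes fallen, chosen in H cows other than the cow scored. Points are cows with their numbers, horizontal lines are group means and the bars beside them span the mean ± SD (n = 3); every H cow lies above every L cow in both panels.

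Before calving, the comparison of H with L asked whether the groups already differed. No gene passed with edgeR among 12696 tested, where the smallest adjusted p was 0.0988 and 439 genes had an unadjusted p under 0.05 against 635 expected. A fit of only the 6 prepartum libraries also called 0 genes, but there 822 had an unadjusted p under 0.05 against 620 expected. The shortfall therefore depended on the fit of 4 groups, and 0 calls do not show that the groups were alike. DESeq2 called 44 genes, 8 higher and 36 lower in H, and limma called 0. Leaving out the prepartum library of L cow 3 gave 1 gene with edgeR.

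At 7 days after calving, 74 of 12696 genes differed between H and L in edgeR's test, 64 higher and 10 lower in H. The higher genes had a median log2 difference of 0.982 and 29 of them differed more than 2-fold. The lower genes had a median of -1.77 and 9 of them differed more than 2-fold. Before calving, the 64 higher genes had a median difference of 0.0255 and 33 of them were higher in H, while the 10 lower genes had a median of -1.64 and 10 were lower in H. Of the 64 higher genes, 62 had also risen after calving in H, where 6.14 would be shared by independent lists of these sizes, and 1 of the 10 lower genes had fallen, where 0.234 would be. In 20 simulations with no effect the list of changes in H was empty each time, so they give no reference value for this overlap. The comparisons share the 3 postpartum H libraries, too few to split, so part or all of the excess may come from them.

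The count of 74 moved widely. It was 0 in a fit of only the 6 postpartum libraries, 18 with library totals as the only scaling (13 higher and 5 lower), and 785 with DESeq2. It was 465 without the postpartum library of H cow 4, and 3 and 1 without that of H cow 5 or 6. It was 4, 0 and 0 without the postpartum library of L cow 1, 2 or 3, and 28 and 19 without the prepartum library of L cow 2 or 3. Without the prepartum library of H cow 4, 5 or 6 it was 17, 14 and 19.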

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

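The scaling by library totals, the length and depth corrections, the fit without cow 5 and the blocked fits of each group's own libraries were chosen after the data had been seen.

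With the cow as a block, 7 genes changed more in H than in L, and this is a difference between the groups that the interaction test called. Their differences of log2 change ranged from 1.73 to 4.48, with a median of 2.02. Of the 7 genes, 6 were also called in H without a block, 7 in H with it, and 3 between H and L after calving. In 1 of them the fitted changes in H and L had opposite directions. With both libraries of cow 5 left out, the blocked test called 0.

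Among 21 sets of 6 values checked for a sample far from the others, 2 were found, where chance gives about 1.05 (5%). The TMM factor of the prepartum library of cow 4 was 1.011, while the others before calving lay between 1.047 and 1.063. The log2 CPM of ENSBTAG00000030814 in the prepartum library of cow 6 was 2.30, while the others before calving lay between 0.34 and 0.95.

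The first pattern weighed is the large number of genes called after calving in H. A trend on gene length does not account for it, since 83.77% of the calls were kept in the same direction with the trend removed, nor does depth, since 87.66% were kept with all libraries thinned to the smallest total. How far the postpartum library of cow 5 sets the count stays open. Without it 706 genes were called, 638 of them among the 1516, which lies between the bounds fixed for a large and a small influence. Leaving out a prepartum H library gave 997, 454 and 543 for cows 4, 5 and 6. Leaving out the postpartum library of cow 4 or 6 gave 2056 and 766. A count as low as 706 was therefore not particular to the postpartum library of cow 5. The stress group, the cow and any difference in the cells of these preparations could each contribute, and cell types were not tested.

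The second pattern is the excess of rises over falls in H. It may come from the choice of scaling, since the share of rises went from 80.4% with TMM to 45.2% with library totals. Library totals moved the median log2 fold change of all genes from -0.00233 to -0.193, so some fall in this share was bound to follow. With median-of-ratios factors it was 74.6%, so the excess was lost under 1 of the 2 other scalings. Which scaling is closer to the RNA content of the cells was not tested.

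The third pattern is that edgeR without a block called 0 genes in L and 1516 in H. DESeq2 called 5 in L and 2314 in H, and edgeR on each group's own libraries with the cow as a block called 1 and 1654. The same change of the same size in L, hidden by the spread between cows, is argued against by a score from 200 risen and 200 fallen genes chosen in H cows other than the cow scored. The scores were 0.798, 0.032 and 0.507 in L cows 1 to 3 and 1.48, 2.55 and 2.06 in H cows 4 to 6, each L score being a mean over 3 gene sets. The highest L score lay below the lowest H score (exact permutation p = 0.1, the smallest possible with n = 3 each). The permutation exchanged the finished scores without choosing the genes again, so this p only describes the order of the cows. A smaller change in the same direction in L stays open, as a hypothesis. The 3 L scores were above 0, none as high as 1.48. In L cow 2, with a score of 0.032, 50.5% of the genes risen in H were higher and 41.8% of those fallen were lower. The interaction test without a block called 0 genes with edgeR, though 133 with DESeq2. With the cow as a block edgeR called 7 genes, all more positive in H, but 0 with both libraries of cow 5 left out. The 0 without a block cannot decide whether the change in L was smaller, since that test recovered 8.96% of the 2-fold changes in simulation. With 3 cows per group, the stress group cannot be separated from other differences between these cows.

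Other splits of the libraries bear on whether the counts exceed chance. For 6 against 6 libraries, 4 of 100 splits gave at least the real count of 1 gene, which is under 5%, but the highest other count was 2466. That split was the real one with H_pre cow 4 in place of L_post cow 2. H_pre cow 4 stood with L_post cows 1 and 3 and H_post cows 4, 5 and 6. The split thus kept most of the contrast in time, so its count does not measure chance alone. L cow 2 changed little between the times (0.809% of genes over 2-fold), and leaving out its postpartum library gave 1035 genes. Whether a structure of the samples other than time added to the 2466 stays open. On the second principal component H_pre cow 4, L_post cow 3 and H_post cows 4 and 6 scored -36.64, -25.5, -39.33 and -31.35. L_post cow 1 and H_post cow 5 scored 11.21 and 6.895, and the libraries on the other side between 10.36 and 32.48. Among the 32 splits that exchange times within cows, 1 gave as many genes as the real split, which is the real split itself and under 5%, and the highest other was 0. These splits used the fit without a block. With the cow as a block the real count was 0, so chance is not excluded in that fit. The comparisons of 3 against 3 have 10 splits, too few for a share under 0.05. The real and highest other counts were 1516 and 0 for the change in H, 74 and 409 for H against L after calving, and 0 and 0 for the change in L, for H against L before calving and for the interaction. As many genes as in the real split were called in 1, 2, 10, 10 and 10 of the 10 splits. In H, 3 of the other splits also part all 3 pairs, and they called 0. For the blocked interaction the counts were 7 and 0. The split with 409 genes set L_post cows 1 and 2 with H_post cow 5 against the rest, which points to a structure of the samples. Those libraries scored 11.21, 32.48 and 6.895 on the second principal component. L_post cow 3 and H_post cows 4 and 6 scored -25.5, -39.33 and -31.35, so this component cut across the stress groups after calving.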

How the results depend on the processing

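Scaling by library totals, the fits without cow 5, the length correction, the thinning, the blocked fits of each group's own libraries and the sign flips within cows were chosen after the data had been seen; the other alternatives were planned. Counts of called genes follow, and causes were not tested unless stated. DESeq2 gave 644 (after against before calving, 6 cows), 5 (change in L), 2314 (change in H), 133 (interaction), 44 (H against L before calving) and 785 (H against L after calving). The replicate block gave 0 over 6 cows, 2460 in H and 7 for the interaction, and in the fit of 12 libraries it changed no other call; with cow 5 also left out the counts were 0, 637 and 0. Without the low-count filter 5 genes were called over 6 cows, 1 for H against L before calving and 48 after it. The group as a covariate gave 2 over 6 cows. A fit of only the groups compared gave 287 in H and 0 in L, or 1654 and 1 with the block, and 0 for H against L after calving. For H against L after calving, median-of-ratios factors gave 41, limma on log2(FPKM + 0.1) gave 29, library totals gave 18 and the cow as a random effect gave 52. Leaving out a library gave 0 to 1035 over 6 cows, 0 to 0 in L, 454 to 2056 in H, 0 to 0 for the interaction, 0 to 1 for H against L before calving and 0 to 465 after it. Without the prepartum library of L cow 3, 1 gene was called before calving.

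Library totals as the only scaling moved the median of all genes by over 0.1, to -0.119 over 6 cows, -0.193 in H, -0.133 for the interaction and -0.113 for H against L after calving. The length correction gave 1475 and thinning 1428 genes in H. Totals after and before calving differed by 1.23 M in the internally scaled fragments (exact permutation p = 0.00433, adjusted 0.0541), against 1.53 M raw. The scaled fragments are already normalized, so their totals do not measure sequencing depth. With the cow as a block, by sign flips within cows, the raw difference of 1.53 M had an exact permutation p of 0.219, and 4 of 6 cows were higher after calving. The scaled totals were higher in 6 of 6 cows (exact sign-flip permutation p = 0.0312, adjusted 0.052). ENSBTAG00000017866 kept its call in 24 of 24 alternatives, ENSBTAG00000030814 and ENSBTAG00000021807 in 19 each, and ENSBTAG00000046218 over 6 cows in 11 of 21. The gene list alternatives were not run, because no identifier matched a name. Depth limits the fold of ENSBTAG00000017866, which had 5 fragments before calving in H: the 95% counting interval of the ratio runs from 71.4 to 517, and the fitted log2 fold change of 7.28 became 10.71 with libraries thinned and 6.45 without the postpartum library of cow 5.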

Other observations

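The tests of differences present before calving were chosen after the result was seen. The genes that separated H from L after calving may be of 2 kinds. The 10 genes lower in H had a median difference of -1.645 before calving, close to the -1.77 after it, so a difference between these cows that calving did not bring about is a candidate explanation for them. The 64 higher genes had a median of 0.02553 before calving, which argues against that explanation for the higher genes as a set. Of the 74 genes, 14 had an unadjusted p under 0.05 before calving, against 439 of all 12696 tested, and edgeR called 0 genes then. Genotype, age or other differences between these 6 cows were not tested.

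The spread between cows was widest in H after calving, with a coefficient of variation of 31.8%, against 17.1% in L before calving, and no test of this difference was made. It rested largely on cow 5. The postpartum library of cow 5 had a chi-square per degree of freedom of 157.3 with that of cow 4 and 112 with that of cow 6. Cows 4 and 6 had 31.23, against 32.47 to 74.77 for pairs in L after calving. Among the L cows, cow 2 changed least between the times, with 0.809% of genes over 2-fold and a score of 0.032.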
